A study of Mus musculus with 2 samples.

How the data were processed

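ATAC-seq peak lists were used from 2 libraries of mouse blood neutrophils, replicates 1 and 2, whose numbers come from the labels. The labels give the lists on mm10 (GRCm38), and each list named only the 21 assembled chromosomes except 1 ranked list. The reference here was GRCm38.p6 with GENCODE release M21, the same build; every listed peak on the assembled chromosomes lay within their lengths there, so coordinates were used without conversion and are given counting from 1. The aligner, the peak caller, the version of each, and how reads were shifted for the transposase are not given in the sources used here. Signal tracks and alignments that the file headers list were not used here. Because no read counts were used, the depth of the libraries is unknown, and differences in the number of peaks between replicates can come from depth as well as from the cells.

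The deposited lists hold, for each peak, its start and end, a signal value in column 7, a −log10 p in column 8 and the offset of its summit in column 10. The signal value is a score that the authors' processing gave to each peak, and neither the labels nor the file headers define it. The −log10 p of each peak is the authors' value too, and the file headers name no test behind it. Per the file headers, each replicate has a list thresholded by the irreproducible discovery rate (IDR), used as the main list, and a less strict list of peaks found in pseudoreplicates. The authors also deposited lists made from both replicates together, of which the conservative IDR list, called here the list passing IDR between replicates, was used to rank peaks and as an alternative. A ranked list of 56758 peaks gives −log10 IDR in column 12, per the file headers, and 33292 of its peaks passed an IDR of 0.05.

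From these lists, overlapping intervals were merged into regions, each with the highest signal value and that peak's summit. Overlap between replicates needed at least 1 bp and was set beside 100 shuffles along the same chromosomes. A summit was called promoter within 1 kb of any annotated start site, and otherwise exon, intron or intergenic. A gene was open when a region of both replicates overlapped 1 kb on either side of any of its start sites. Distal regions had summits over 1 kb from every start site and were counted within 50 kb of the 5'-most start site of a gene. A promoter was CpG-rich when the 500 bp on either side of that site had an observed-to-expected CpG ratio of at least 0.6 and a GC share of at least 0.5. Windows of 101 bp around each summit were searched on both strands for 25 fixed motif strings and compared with windows 1 kb upstream and downstream that overlapped no peak. Fixed strings find fewer sites than weight matrices and cannot separate factors of a family.

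The 22 gene lists, the motifs, the tests and the rule for the genes named in the text were fixed before the data were examined. The lists held 397 entries, of which 395 matched a protein-coding gene of the annotation; Clec7a and Ahsp did not match under these symbols. The rule named, for each of 7 neutrophil lists, the 3 members with the highest mean signal value at their promoters and up to 3 members, in alphabetical order, with no promoter peak. For the other lists it named 2 of each. It also named the genes of the 10 strongest promoter peaks in the list passing IDR between replicates and the 5 genes with the most distal regions. Some genes that the rule names are not reported here. Genes named outside the rule are said to be so. The comparison of motifs between the strongest and the weakest deciles of regions was added after the data were examined.

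With 1 group of 2 replicates there was no comparison between groups of samples. Shares are given with 95% Wilson intervals, which cover counting error only, and means over replicates with their SD. Gene lists at promoters and motifs at summits were tested with the 2-sided Fisher's exact test, and distal regions with 100000 random gene lists, 2-sided, with a smallest possible p of 2.00e-05. Adjusted p values are Benjamini-Hochberg, over the 22 lists, over all lists and classes for CpG classes, and over the 25 motifs within a replicate and class of region; the threshold was 0.05. Where a p was too small to be represented, odds ratios are given in its place. Alternatives were the less strict lists, peaks at or above a list's median signal value (called the stronger peaks), other overlap minimums, a promoter width of 2.5 kb, the 5'-most start site alone, the list passing IDR between replicates, backgrounds of the same CpG class or gene density, a distal window of 100 kb, motif windows of 100 bp on either side of the summit, dinucleotide shuffles, and each replicate alone.

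The tests were tried on simulated data first. For promoter lists, 20 of 20 planted lists and 4 of 200 null lists were called higher among 21911 genes, and for distal regions 20 of 20 and 4 of 100. Simulated lists were called at an unadjusted p under 0.05, so calls after adjustment were not tried. The planted promoter lists were far more open than other genes, so smaller differences were not tried either. The simulated distal counts were independent between genes, so regions shared by neighbouring genes were not tried. The motif test called the 1 planted motif and 0 of 24 others, and the count of repeated 31-mers was right for 50 of 50. The simulated summit and background windows had the same base composition, so the effect of a difference in composition was not tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.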

Results

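Open chromatin was mapped in neutrophils, the short-lived phagocytes that are among the first cells to reach an infected tissue. The cells came from the peripheral blood of adult C57BL/6J mice aged 5 to 6 weeks. The assay was ATAC-seq, in which a transposase inserts sequencing adapters where DNA is accessible. The series held 2 libraries of 1 group, biological replicates 1 and 2, each made from 50000 cells. Their size ranges, given without a unit, were 151 to 347 in replicate 1 and 151 to 379 in replicate 2. There was no second cell type, condition or time point, so the comparisons below are between replicates, between parts of the genome and between groups of genes. The labels give each replicate its own biosample record and both the same donor record, and they do not say whether the cells came from separate mice. The spread between the replicates, and any p-value resting on it, may therefore be technical. Sex was not collected, and no sorting or purification step is named. Total read counts were not used here, so the depth of each library is unknown.

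Replicate 1 had 27709 open regions and replicate 2 had 14548, from 34409 and 18367 listed peaks whose overlapping intervals were merged. The regions of replicate 1 had a median width of 364 bp (range 150 to 2912 bp) and covered 11.8 Mb, or 0.435% of the assembled chromosomes. Those of replicate 2 had a median width of 438 bp (range 150 to 1763 bp) and covered 6.78 Mb, or 0.249%. Replicate 1 had 604 regions on chromosome X and 10 on chromosome Y, and replicate 2 had 316 and 8. Nearly every region of replicate 2 was also open in replicate 1. Of its 14548 regions, 14249 overlapped a region of replicate 1 by at least 1 bp, or 97.9% (95% Wilson interval 97.7 to 98.2). In the other direction 14274 of 27709 regions overlapped, or 51.5% (50.9 to 52.1). When the other list was shuffled along the same chromosomes 100 times, the overlap averaged 1.02% and 0.532% and never exceeded 1.25% and 0.704%.

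The regions found in replicate 1 alone were narrower and less often at promoters. These 13435 regions had a median width of 291 bp, against 470 bp for the shared ones, and 24.7% lay at a promoter, against 61.8%. Their median signal value in replicate 1 was 8.19, against 12.4. The signal value is the authors' own score for a peak, without a stated definition in the sources used here, and it serves below only to describe and rank peaks within a list. Of these regions, 9324 (69.4%) overlapped a peak of the less strict list of replicate 2. Replicate 2 alone had 299 regions, of which 67.2% lay at a promoter and 261 overlapped a peak of the less strict list of replicate 1. Across the 14274 shared regions, the signal values of the replicates had a Spearman rho of 0.771 and a Pearson r of 0.781 on the log2 scale. These correlations are across regions of 2 libraries, and regions are not independent replicates.

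Gene promoters took up the largest share of open regions in both libraries. In replicate 1, 12144 of 27709 summits lay within 1 kb of an annotated transcription start site, or 43.8% (95% Wilson interval 43.2 to 44.4). In replicate 2, 9027 of 14548 did, or 62.0% (61.3 to 62.8). The mean was 52.9% ± 12.9 (SD, n = 2). The shares were 7.03-fold and 9.91-fold those found after shuffling the regions of replicate 1 and replicate 2. Introns held 23.1% ± 7.03 of summits and intergenic sequence 21.2% ± 5.00 (SD, n = 2), both below the shuffled shares of 39.3% and 51.2% in replicate 1. Exons outside promoters held 2.77% ± 0.860 (SD, n = 2), with 3.38% in replicate 1 against a shuffled mean of 3.33% and 2.17% in replicate 2 against 3.35% (shuffle range 2.98 to 3.75). The intervals cover counting error alone, and the 2 replicates differed in promoter share by more than that error.

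**Figure D1:**
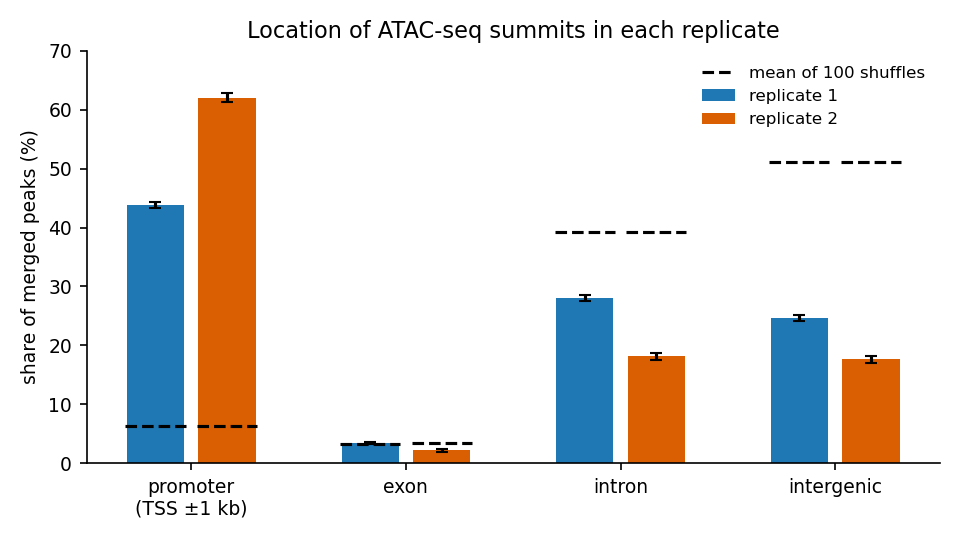
Share of open regions (vertical axis, percent of regions) whose summit lay in a promoter, another exon, an intron or intergenic sequence, with 1 bar per replicate, 95% Wilson intervals as whiskers and the mean of 100 shuffles as dashed lines. Promoters held 43.8% of the regions of replicate 1 and 62.0% of those of replicate 2, far above the shuffled shares of 6.23% and 6.26%.

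None of the 10 strongest promoter peaks was at a gene of the neutrophil lists used below. Among peaks passing the irreproducible discovery rate (IDR) between the replicates, the highest signal value at a protein-coding promoter was at Vbp1, which encodes a subunit of the chaperone prefoldin. That peak lay at chromosome X, 75514058 to 75514935, with its summit 58 bp from the start site, and had a signal value of 29.55 (26.99 in replicate 1 and 23.86 in replicate 2). Nuf2, a kinetochore gene, followed with 28.8 at chromosome 1, 169531324 to 169531898. The next were Pnpt1 (28.6), the shared promoter of the spindle gene Nusap1 and Oip5 (28.2), Pigu (28.0), Gm5141 (27.9), the spindle gene Tpx2 (27.5), Platr25 (27.4), Glipr1l3 (27.2) and the DNA helicase-like factor Hltf (27.2).

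Promoters were then compared between groups of genes, to see which functions of the neutrophil and which other cell types had open promoters. A gene counted as open when both replicates had a region overlapping 1 kb on either side of any of its start sites. By this measure 8710 of 21911 protein-coding genes were open, or 39.8%; replicate 1 alone gave 10315 (47.1%) and replicate 2 alone 8825 (40.3%). Each of 22 gene lists was tested against all other protein-coding genes with a 2-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Of these, 4 were open more often and 7 less often than other genes. Genes are not independent replicates, so each test describes these libraries.

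Among the lists of neutrophil function, the transcription factors of myeloid cells were open more often than other genes, at 17 of 24 (70.8%, adjusted exact p = 0.0075). Their highest signal values were at Nfe2 (14.6 in replicate 1 and 15.9 in replicate 2), Max (12.7 and 16.6) and Stat3 (12.9 and 14.8). The highest Stat3 peak in the list passing IDR between replicates lay in a noncoding exon, away from the 5'-most start site. Cebpb, a factor of myeloid gene control, and Fli1, of the ETS family, had no promoter peak in either list. This call did not hold with the 5'-most start site alone (58.3%, adjusted exact p = 0.061) or against genes of the same CpG class (adjusted exact p = 0.062), and with the stronger peaks alone the share turned below other genes (29.2%, adjusted exact p = 1).

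The mature neutrophil list, of surface receptors and abundant cytosolic proteins, was open at 17 of 32 genes (53.1%), which did not pass the test (adjusted exact p = 0.203). Clec4e, a receptor for fungal and mycobacterial glycolipids, had the highest values of the list (19.1 and 16.2). It was followed by Tlr4, the receptor for bacterial lipopolysaccharide (15.5 and 14.7), and Itgb2, the shared beta chain of leukocyte integrins (13.3 and 14.7). Cd14, Csf2rb and Fpr1 had no promoter peak in either list, although Csf2rb had one with a signal value of 6.36 in the list passing IDR between replicates. In replicate 1 alone 25 of the 32 genes were open (78.1%), and the list then passed the test (adjusted exact p = 0.0017), as it did under 3 other alternatives. S100a9, which encodes a subunit of calprotectin, was open in both replicates (7.36 and 10.1), and its partner S100a8 was open in replicate 1 alone (9.53); this pair was picked after the values were seen.

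Granule genes were not open more often than other genes. The primary granule list, of proteins packed early in bone marrow precursors, had 5 of 14 genes open (35.7%, adjusted exact p = 1). Ctsc, the cathepsin that activates granule serine proteases, led with 16.1 and 16.3, followed by Gstm1 (8.59 and 10.03) and the bactericidal protein gene Bpi (10.4 and 7.13). Cd63, Clec5a and Ctsg had no promoter peak, and neither did Mpo, Elane, Prtn3 and Ms4a3, which are named here after their values were seen. The secondary and tertiary granule list had 6 of 22 genes open (27.3%, adjusted exact p = 0.342). Arg2 (15.0 and 15.5), the metalloprotease Adam8 (14 and 14.4) and the neutrophil collagenase gene Mmp8 (13.9 and 11.6) had its highest values, and Camp, Cd177 and Chil3 had none.

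Because primary granule genes are transcribed in precursors and the mature list in circulating cells, these lists were also compared directly. The primary granule share was 17.4 points lower, but the difference did not pass the exact test (−17.4 points, 95% interval −42.5 to 13.1, Fisher's exact p = 0.346). With the less strict lists of each replicate it did, at −34.4 points (exact p = 0.0266). Primary granule genes and secondary and tertiary granule genes differed by 8.44 points (95% interval −20.0 to 37.6, Fisher's exact p = 0.716), so a sizeable difference in either direction was not excluded.

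The NADPH oxidase, the enzyme that makes superoxide in phagocytes, had 6 of 8 genes open (75%, adjusted exact p = 0.103). Ncf4, which encodes a cytosolic subunit (9.17 and 10.8), and the GTPase gene Rac2 (9.67 and 10.1) were among the open genes. In replicate 1 all 8 were open, and the list then passed (adjusted exact p = 0.0053), as it did under 3 other alternatives. Of the inflammatory cytokine and NF-kB response list, 12 of 25 genes were open (48.0%, adjusted exact p = 0.485); against genes of the same CpG class the list passed (adjusted exact p = 0.0465). Sod2, the mitochondrial superoxide dismutase (16.7 and 15.0), and Tnfaip3 and Nfkbiz, which regulate NF-kB signalling (12.4 and 13.9, and 10.7 and 14.4), led it, while the chemokine genes Ccl2, Ccl3 and Ccl4 had no promoter peak. Of the interferon response list, 11 of 20 were open (55.0%, adjusted exact p = 0.228), among them the signalling gene Stat2 (21.3 and 20.4) and Usp18 (13.3 and 15.1). Ifi44, Ifitm3 and Isg15 had none. In replicate 1 alone 17 of the 20 were open and the list passed (adjusted exact p = 0.0028), as it did under 3 other alternatives.

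Housekeeping, cell cycle and apoptosis genes were open more often than other genes. All 16 housekeeping genes were open (adjusted exact p = 8.48e-06), with the highest values at Pgk1 (19.6 and 21.9) and Rplp0 (19.4 and 20.3). Of the cell cycle list, 17 of 18 were open (94.4%, adjusted exact p = 1.89e-05). Pcna, the sliding clamp of replication, had 18.58 and 19.04, and the checkpoint kinase gene Bub1 had 19.9 and 16.6. Plk1 was the exception, and it had a peak of 7.89 in the list passing IDR between replicates. Of the apoptosis and survival list, 13 of 16 were open (81.2%, adjusted exact p = 0.0043), among them Bcl2l1 (11.0 and 11.6). With the stronger peaks alone the apoptosis share was 18.8% (adjusted exact p = 0.616).

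Promoters of most other lineages were seldom open. No hepatocyte gene of 18 was open (adjusted exact p = 9.68e-04), Alb and Ahsg included, and no erythroid gene of 17 (adjusted exact p = 0.0013). The erythroid regulator gene Tal1 had a peak in replicate 1 alone (8.56). Of the natural killer cell list, 0 of 15 were open (adjusted exact p = 0.0033), with peaks in replicate 1 alone at Prf1 (11.7) and Klrd1 (8.403). The neuron list had 1 of 18 open (adjusted exact p = 0.0075), the synaptic vesicle gene Syn1 (20.4 and 17.5). The T cell list had 2 of 20 (adjusted exact p = 0.013), Cd3d (16.9 and 17.8) and Gata3 (8.46 and 10.9), and neither Bcl11b nor Cd247. With the 5'-most start site alone, neither Cd3d nor Gata3 was open, and the T cell list had 0 of 20 (adjusted exact p = 0.0015). The megakaryocyte and platelet list had 1 of 15 (adjusted exact p = 0.0145), Itgb3 (14.7 and 12.8). The eosinophil, basophil and mast cell list also had 1 of 15 (adjusted exact p = 0.0145), Hdc (9.79 and 9.92), which makes histamine. Hdc was not open with the 5'-most start site alone, which left that list at 0 of 15 (adjusted exact p = 0.0058). Against genes of the same CpG class, the T cell list (adjusted exact p = 0.152), the megakaryocyte list and the eosinophil list (both adjusted exact p = 0.252) were no longer past the threshold. They also missed it in replicate 1 alone (adjusted exact p = 0.0969 for T cells and 0.0582 for the others), and with the less strict lists the T cell (0.0568), natural killer cell and megakaryocyte (both 0.0552) lists missed it, as the megakaryocyte list did with the stronger peaks (0.104).

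The remaining lists of other cell types did not pass the test. The B cell list had 11 of 18 genes open (61.1%), with the highest values at the complement receptor gene Cr2 (23.7 and 17.0) and the adaptor gene Bank1 (18.5 and 12.5). Blk and Fcmr had none. The list did not pass the test (adjusted exact p = 0.131), but it did in replicate 1 alone, with 15 of 18 (adjusted exact p = 0.0065), and under 4 of the other alternatives. The dendritic cell and MHC class II list had 6 of 14 (42.9%, adjusted exact p = 0.871), led by H2-DMa (16.23 and 18.01) and Tcf4 (11.8 and 16.6), with none at Batf3 or Cd209a. The monocyte and macrophage list had 3 of 18 (16.7%, adjusted exact p = 0.0905), among them Maf (11.6 and 12.5) and Nr4a1 (8.12 and 12.2), and none at Adgre4 or Ccr2. The stem and progenitor cell list had 6 of 16 (37.5%, adjusted exact p = 1), among them Meis1 (12.2 and 8.99). The skeletal muscle list had 2 of 16 (12.5%, adjusted exact p = 0.0685), Mylpf (10.4 and 11.9) and Tnni2 (10 and 8.41), and none at Acta1. It passed as less often open in replicate 1 alone (adjusted exact p = 0.0094), in replicate 2 alone (0.0414) and under 3 other alternatives (0.0375 to 0.039), and the monocyte list did so with the stronger peaks (0.0482) and a promoter width of 2.5 kb (0.0493).

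**Figure D2:**
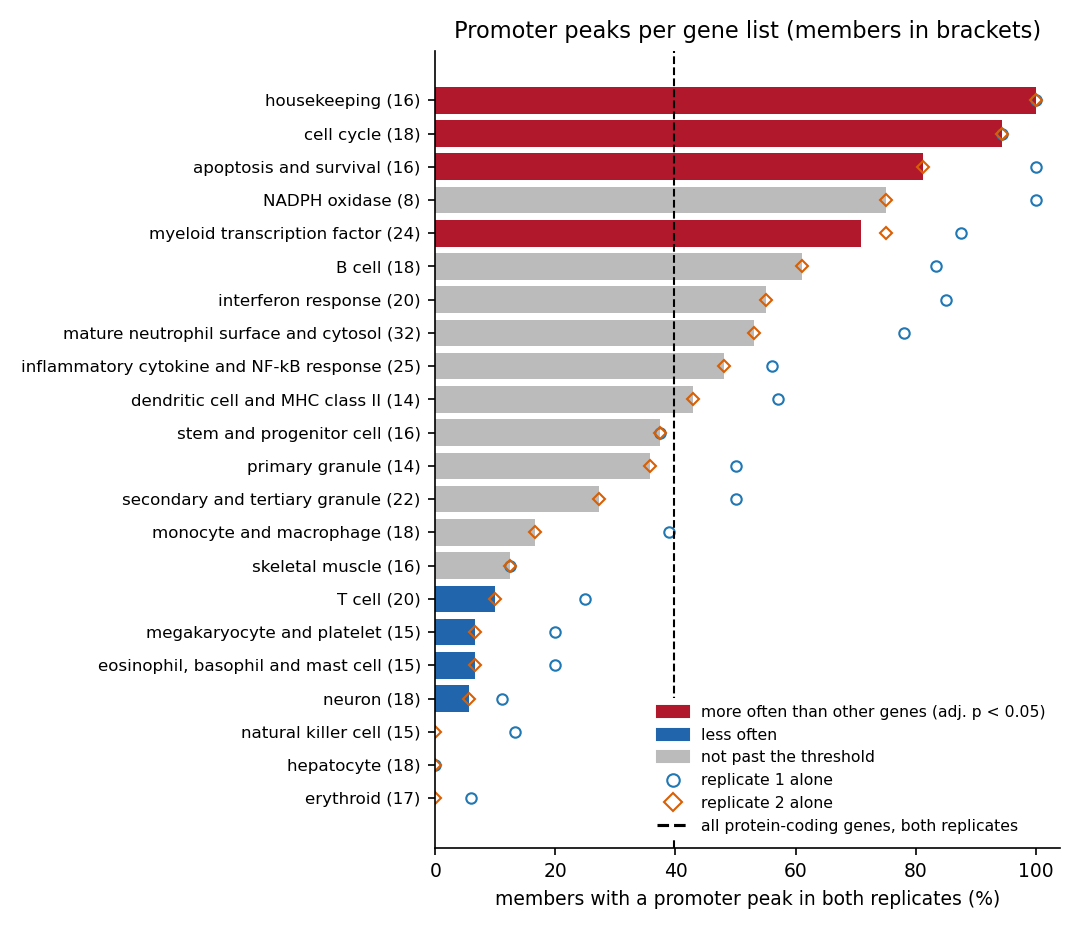
Percent of the genes of each of 22 lists with a promoter peak in both replicates (bars, red for more often than other genes, blue for less often, grey for not past the threshold), with the share in replicate 1 (circles) and in replicate 2 (diamonds) and the share of all protein-coding genes as a dashed line at 39.8%. Housekeeping and cell cycle genes reach 100% and 94.4%, and the hepatocyte, erythroid and natural killer cell lists lie at 0.

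CpG-rich promoters are open in most cell types, so the lists were also compared within CpG classes. Of 9723 genes with a CpG-rich promoter 6492 were open, or 66.8% (95% Wilson interval 65.8 to 67.7), and of 12188 other genes 2218 were open, or 18.2% (17.5 to 18.9). In the second class, which holds most genes of the granule, mature neutrophil and NADPH oxidase lists, 7 lists stood above the other genes. All 5 housekeeping genes of this class (adjusted exact p = 0.0030) and all 3 cell cycle genes (adjusted exact p = 0.0367) were open. The mature neutrophil list had 14 of 29 genes of this class open (48.3%, adjusted exact p = 0.0030) and the interferon response list 9 of 18 (50%, adjusted exact p = 0.0184). The NADPH oxidase list had 5 of 7 (adjusted exact p = 0.0216) and the myeloid transcription factors 5 of 8 (adjusted exact p = 0.0367). The B cell list lies wholly in this class, and its 11 of 18 passed here (adjusted exact p = 0.0027). The primary granule list, with 5 of 13 (adjusted exact p = 0.213), and the secondary and tertiary granule list, with 5 of 21 (adjusted exact p = 0.702), did not. In the CpG-rich class the neuron list was low, at 1 of 10 (adjusted exact p = 0.0037).

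Distal open regions lay more densely around the genes of 11 lists than around random genes, among them the mature neutrophil, NADPH oxidase and myeloid transcription factor lists. Over all protein-coding genes the mean was 0.801 ± 0.521 distal regions within 50 kb of the 5'-most start site (SD, n = 2), with 1.17 in replicate 1 and 0.433 in replicate 2. The mature neutrophil list had 2.89 ± 1.79 (SD, n = 2), or 3.61-fold the mean of random lists. Each of its 32 genes had at least 1 in replicate 1, and 23 did in replicate 2. Of all 21911 protein-coding genes, 10641 had none in either replicate. The dendritic cell and MHC class II list had 3.32 ± 1.36 (4.15-fold), the NADPH oxidase list 2.94 ± 1.68 (3.68-fold), the myeloid transcription factors 2.44 ± 1.39 (3.04-fold) and the inflammatory list 2.22 ± 1.10 (2.77-fold), all SD over the 2 replicates. Cebpb and Fli1, without a promoter peak, each had 7 distal regions on average, with 9 and 5 at Cebpb and 10 and 4 at Fli1.

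Each list was compared with 100000 random lists of as many protein-coding genes, and 11 of the 22 lists had more distal regions at an adjusted p under 0.05. Neighbouring members of a list can count the same distal regions, as the adjacent genes Ccl3 and Ccl4 may, with 3 and 1 each. Random lists of scattered genes do not reproduce this, so the p values of lists with clustered genes may be too small. The adjusted p was 1.10e-04 for the mature neutrophil, dendritic cell, myeloid transcription factor and inflammatory lists, whose unadjusted p of 2.00e-05 was the smallest the random lists can give. It was 7.92e-04 for the NADPH oxidase list. The B cell list followed with 1.92 ± 1.38 (2.39-fold, adjusted permutation p = 0.0027), then the megakaryocyte list (2.25-fold, adjusted permutation p = 0.016), the eosinophil list (2.16-fold, adjusted permutation p = 0.0221), the primary granule list (2.05-fold, adjusted permutation p = 0.0444), the secondary and tertiary granule list (1.98-fold, adjusted permutation p = 0.016) and the apoptosis list (1.95-fold, adjusted permutation p = 0.0457). With replicate 2 alone, the primary granule list (adjusted permutation p = 0.0661), the secondary and tertiary granule list (0.238), the apoptosis list (0.098) and the B cell list (0.0735) no longer passed, which leaves 7 lists. The primary granule call was also lost with replicate 1 alone (adjusted permutation p = 0.0583) and under 3 other alternatives, the NADPH oxidase (0.0747) and apoptosis (0.11) calls with the stronger peaks alone, and the megakaryocyte (0.053) and eosinophil (0.139) calls with the less strict lists.

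The other 11 lists were not past the threshold within 50 kb. Within 100 kb, 15 lists passed, with the interferon response (adjusted permutation p = 0.022), housekeeping (0.0222), natural killer cell (0.0474) and T cell (0.0451) lists among them; in replicate 1 alone interferon response (0.0444) and housekeeping genes (0.0214) passed, and housekeeping genes also with the less strict lists (0.0188). Housekeeping genes had 1.53 (adjusted permutation p = 0.0536), interferon response genes 1.38 (0.0725), natural killer cell genes 1.43 (0.0842), monocyte genes 1.14 (0.299), T cell genes 1 (0.524), cell cycle genes 0.861 (0.849), skeletal muscle genes 0.844 (0.864), erythroid genes 0.647 (0.732) and hepatocyte genes 0.417 (0.186). The neuron list had 0.306 and the stem and progenitor list 0.281, each with an adjusted permutation p of 0.0667; their unadjusted p of 0.0422 and 0.0424 were the only ones under 0.05 among lists below the random mean, so that 0 lists were lower after adjustment. Of single genes, Klrb1c, a natural killer cell receptor gene on chromosome 6, had the most distal regions, 10 and 7 in the 2 replicates, and no promoter peak. Ube2v1, on chromosome 2, followed with 9 and 7, and its 50 kb window overlaps that of Cebpb, so the same regions may count for both. Acod1, which makes itaconate in activated myeloid cells, the antiproliferative gene Btg2 and the chemokine receptor gene Ccr1 each had 10 and 5, and came first in the alphabet among 13 genes tied at a mean of 7.5.

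**Figure D3:**
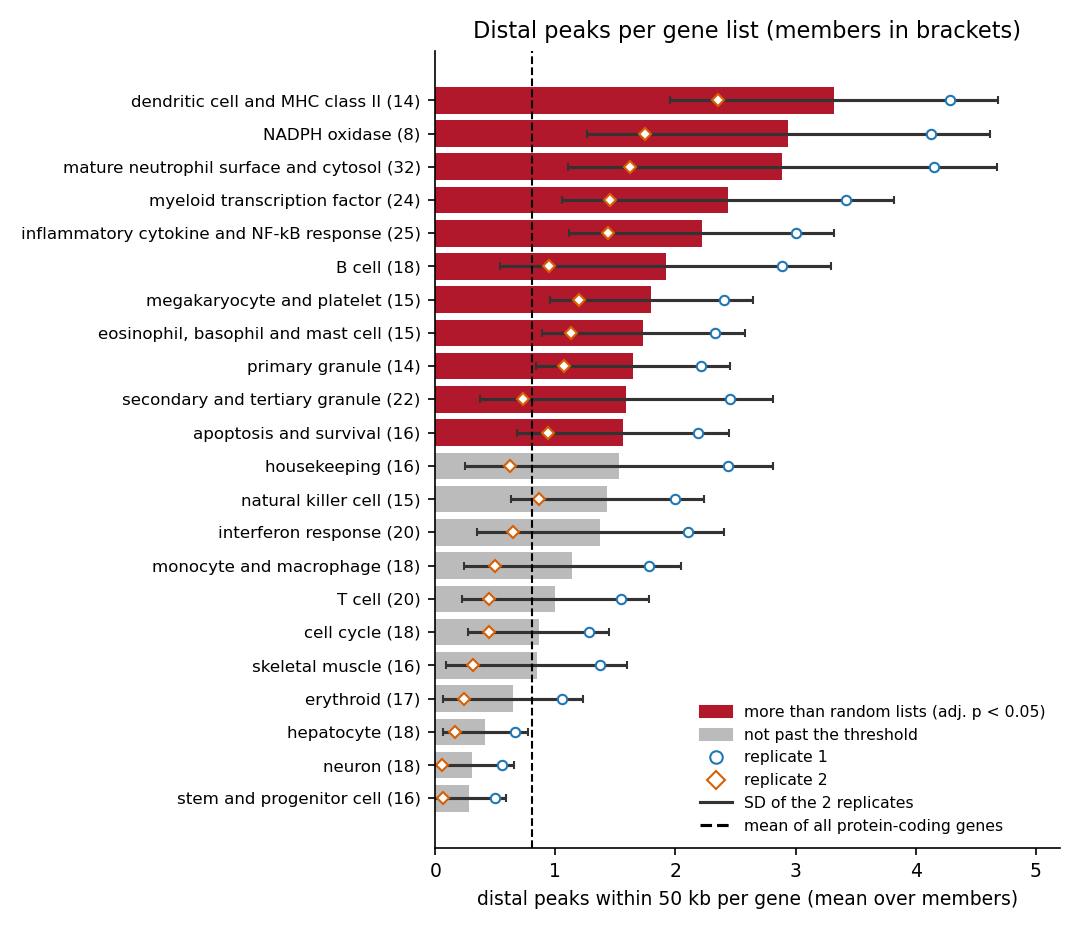
Mean number of distal open regions within 50 kb of the start site per gene (horizontal axis) for each of 22 lists, averaged over the 2 replicates, with whiskers for their SD, a point per replicate and a dashed line at the mean of all protein-coding genes, 0.801. The dendritic cell and MHC class II (3.32), NADPH oxidase (2.94) and mature neutrophil (2.89) lists lie highest, and replicate 1 lies above replicate 2 in each list.

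Sequence motifs at the summits differed between distal regions and promoters. The strings were counted within 50 bp of each summit and compared with windows 1 kb away that overlap no peak. At distal summits the motif of CTCF, the protein that anchors chromatin loops, was the most frequent of the 25 tested, at 12.6% ± 1.88 (SD, n = 2) against 0.165% in the flanks, with odds ratios of 97.9 in replicate 1 and 76.6 in replicate 2. PU.1, the ETS factor of myeloid and B cells, followed with 8.83% ± 0.761 against 0.594% (odds ratios 14.3 and 18.3). AP-1 had 6.16% ± 0.742 against 1.76%, RUNX 4.02% ± 0.0259 against 1.15% and CEBP, the motif of the granulocyte factors of that family, 1.98% ± 0.0625 against 0.584%. NF-kB had 1.43% against 0.459%, OCT 1.501% against 0.498%, EBF 0.492% against 0.213% and the interferon element ISRE 1.92% against 1.42%. GATA, the motif of erythroid and mast cell regulators, was less frequent at distal summits than in the flanks (0.702% against 1.34%).

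At promoter summits the motifs of general promoter factors had the largest shares of windows. NFY, which binds the CCAAT box, had 17.7% ± 2.29 against 2.76% in the flanks (SD, n = 2), with odds ratios of 6.83 and 8.38. SP had 9.52% ± 2.28 against 0.555%, KLF 5.58% ± 0.722 against 0.595% and the ETS string 5.52% ± 0.836 against 0.134%. PU.1 had 2.94% against 0.632%, CTCF 2.61% against 0.180%, YY1 1.21% against 0.0472% and NRF1 0.711% against 0.0028%. The strings differ in length, so shares do not rank enrichment. By odds ratio ETS (41.1 and 45.9), YY1 (27.4 and 24.6) and SP (15.9 and 21.8) were among the motifs above NFY. GATA (0.357% against 1.23%), NEUROD (0.854% against 1.35%), TBX (0.186% against 0.464%), TCF/LEF (0.0648% against 0.250%) and HNF4 (0.0469% against 0.236%) were less frequent than in the flanks.

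A motif was called when Fisher's exact test passed in both replicates in the same direction, with Benjamini-Hochberg adjustment over the 25 motifs. By this rule 16 motifs were more frequent and 1 less frequent at distal summits, and 11 were more and 5 less frequent at promoter summits. The larger adjusted p of the replicates was 2.50e-272 for CTCF, 5.20e-178 for PU.1, 5.43e-54 for AP-1, 1.48e-31 for RUNX, 4.39e-16 for CEBP and 3.06e-05 for GATA at distal summits. It was 3.43e-225 for ETS and 6.63e-310 for SP at promoters. Windows are not independent replicates, and with the stronger peaks alone ISRE (adjusted exact p = 0.093), EBF (0.088), NRF1 (0.0758) and YY1 (0.238) at distal summits and CEBP at promoters (0.415) lost their calls. With dinucleotide-preserving shuffles of the summit windows as background, none of the motifs called less frequent remained past the threshold, NF-kB at promoters (adjusted exact p = 1) and NFY at distal summits (0.140) lost their calls, which NFY also did with the less strict lists (0.0713) and with windows of 100 bp to either side (0.119), and the NEUROD difference at promoters turned to 0.223 points (adjusted exact p = 0.596).

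**Figure D4:**
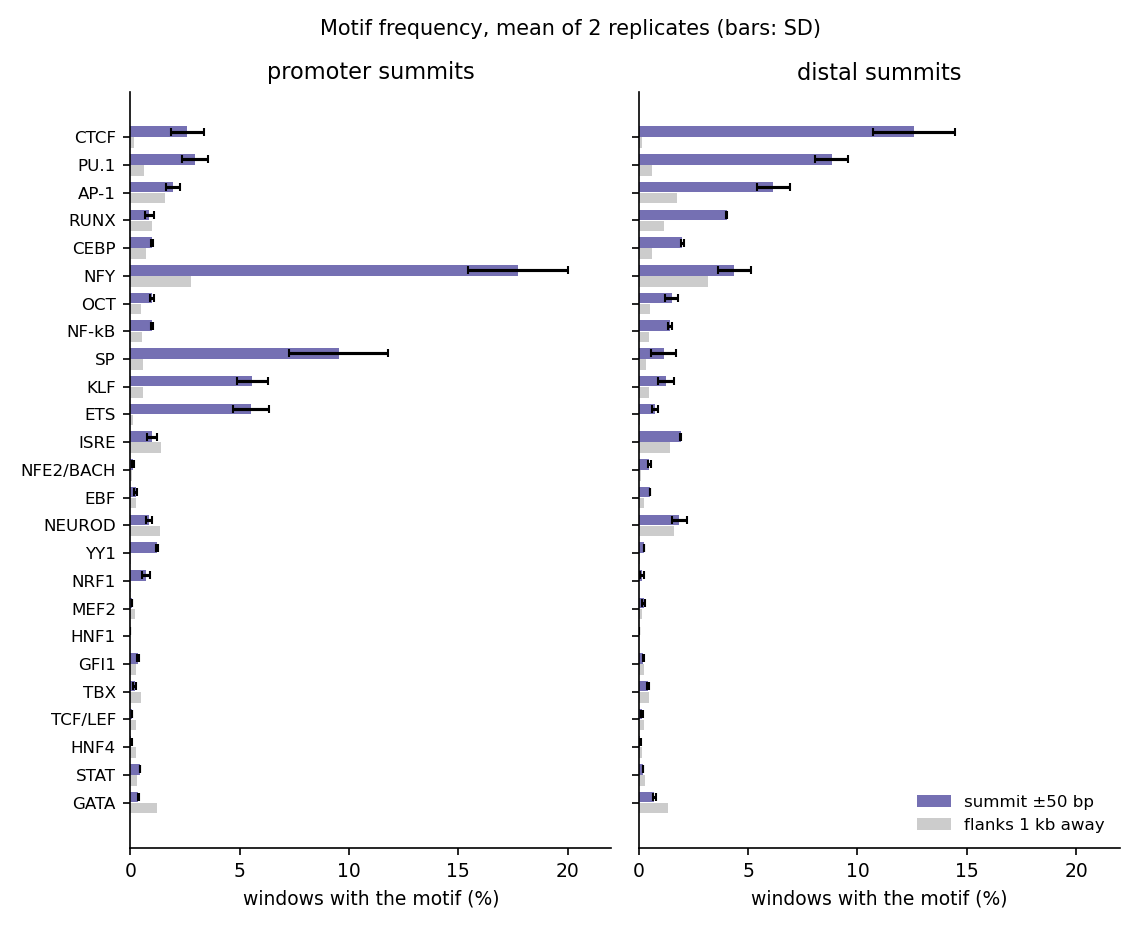
Percent of summit windows (within 50 bp) and of flanking windows with each of 25 motifs, for promoter and distal regions in separate panels, as means of the 2 replicates with SD whiskers. NFY (17.7%) leads at promoters, and CTCF (12.6%) and PU.1 (8.83%) lead at distal regions.

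The sequence at some of the strongest promoter summits of the lists is given as the reference genome has it, 20 bp to either side of the summit, in mm10. At Clec4e the summit lay at chromosome 6, position 123289952, 82 bp upstream of the start site and outside the annotated gene; the sequence from 123289932 to 123289972 is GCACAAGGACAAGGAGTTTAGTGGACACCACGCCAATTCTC, and a CEBP match, TTGCACAA, begins at 123289930. At Nfe2 the summit lay at chromosome 15, position 103258417, 14 bp upstream of the start site, with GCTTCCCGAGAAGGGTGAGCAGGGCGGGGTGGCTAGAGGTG from 103258397 to 103258437. A CEBP match there, TTATGCAA, spans 103258386 to 103258393. At Ctsc the summit lay at chromosome 7, position 88277997, 88 bp upstream of the start site, with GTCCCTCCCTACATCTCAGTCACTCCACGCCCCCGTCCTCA from 88277977 to 88278017 and a KLF match, CCACGCCC, from 88278001. At Stat2 the summit lay at chromosome 10, position 128270450, 109 bp upstream of the start site, with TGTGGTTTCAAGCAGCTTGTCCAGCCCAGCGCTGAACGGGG from 128270430 to 128270470. It holds a RUNX match, TGTGGTTT, at its start and lies between a pair of NFY matches, CCAATCA from 128270410 and CCAATGA from 128270482. The summits of Arg2 (chromosome 12, position 79130770, 7 bp upstream of the start site), Sod2 (chromosome 17, position 13007851, in an untranslated exon) and Cr2 (chromosome 1, position 195176771, 55 bp upstream of the start site) had none of the 25 motifs within 50 bp.

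The share of promoter summits with an NFY or ETS motif differed with the strength of the peak, a comparison added after the data were examined. In the strongest decile of promoter regions of replicate 1, NFY was present in 35.0%, against 5.84% of the weakest decile (adjusted exact p = 6.17e-75, Fisher's test). In replicate 2 the shares were 35.2% and 7.09% (adjusted exact p = 4.47e-50). The ETS motif was in 8.48% of the strongest and 1.32% of the weakest decile in replicate 1 (adjusted exact p = 3.47e-16), and in 7.98% and 3.32% in replicate 2 (adjusted exact p = 2.25e-04). CTCF went the other way at promoters, with 0.906% of the strongest and 4.12% of the weakest decile in replicate 1 (adjusted exact p = 8.36e-06) and 0.665% and 2.99% in replicate 2 (adjusted exact p = 0.0032). At distal regions PU.1 was in 10.8% of the strongest and 6.29% of the weakest decile in replicate 1 (adjusted exact p = 1.12e-04). The shares in replicate 2 were 11.4% and 7.23%, which did not pass after adjustment over the 100 tests of this kind (adjusted exact p = 0.103).

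**Figure D5:**
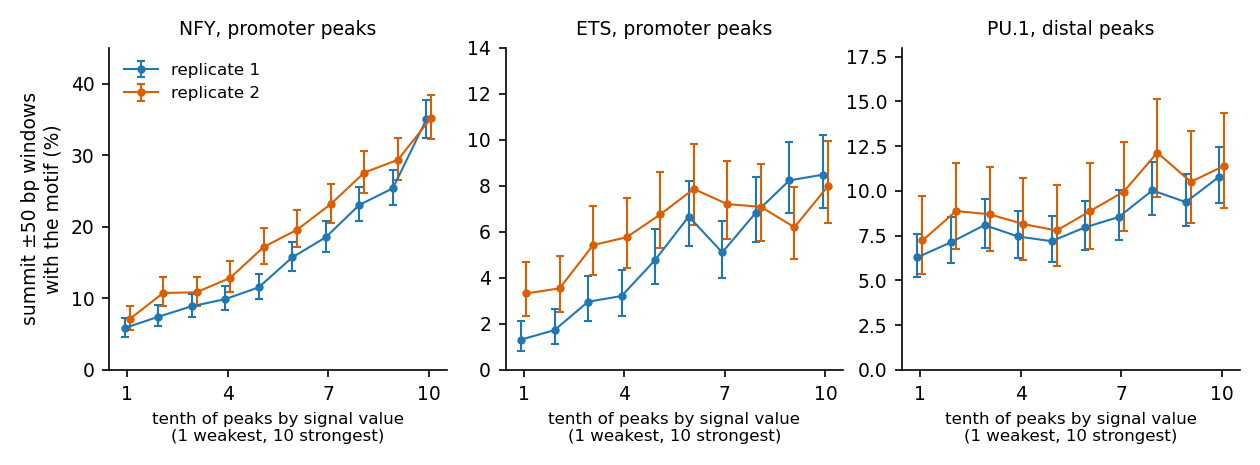
Percent of summit windows with a motif (vertical axis) by decile of signal value from weakest to strongest (horizontal axis), for NFY and ETS at promoters and PU.1 at distal regions, with 1 line per replicate and 95% intervals. NFY goes from 5.84% to 35.0% in replicate 1 and from 7.09% to 35.2% in replicate 2.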

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

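Among the peak lists outside the main comparisons, 2 held signal that those comparisons do not use. The IDR-thresholded list that the authors made from both replicates together had 32225 regions, and 4877 of them (15.1%) overlapped no region of the main list of either replicate. These regions had a median signal value of 6.27, and 27.0% lay at a promoter. Of them, 4791 overlapped a region of the less strict list of a replicate, and 86 overlapped none. The IDR-ranked list had 244 of its 56758 peaks on sequences outside the 21 assembled chromosomes, where the other lists have no peak. No explanation was tested for either result.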

How the results depend on the processing

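Of 100 alternative values of the main results, 65 counted as unchanged, 34 moved by more, and 1 passed a threshold it had missed. Unchanged meant on the same side of the threshold, within the error or, for counts, within a fixed factor of the main value. Except where the construction of an alternative shows it, the cause of a move was not tested. Of the 2 alternatives added after seeing the data, the B cell against the T cell list restates a contrast already seen. Equal numbers of the strongest peaks raised the promoter share of replicate 1 from 43.8% to 51.2%. Replicate 2 stayed at 62.0%. The mean, 56.6%, counted as unchanged because it moved by less than the SD of the replicates (12.9). That rule could hardly fail here, and for location it cannot fail when a replicate is left out. No paired analysis was possible because there is 1 group. Depth is unknown, so that a missing peak does not show closed chromatin.

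With the less strict lists, which hold more peaks, replicates 1 and 2 had 47640 and 29848 regions, overlaps of 60.05% and 96.2%, a rho of 0.811, 7 lists with more promoter peaks in place of 4, and open shares of 78.8% (CpG-rich) and 26.6% (other promoters); the primary granule minus the mature neutrophil share was −34.4 points (exact p = 0.0266). With the stronger peaks alone, which are fewer, there were 16581 and 8925 regions, overlaps of 52.1% and 96.7%, a rho of 0.633, 2 lists with more promoter peaks, and open shares of 52.7% and 12.7%. Myeloid transcription factors (29.2%, adjusted exact p = 1) and apoptosis genes (18.8%, adjusted exact p = 0.616) then turned below other genes. Overlap of at least 50% gave 50% and 97.2%, with a rho of 0.779 where both peaks had to meet it. Equal numbers of the strongest peaks gave overlaps of 74.6% and 75.1%, and −log10 p in place of the signal value a rho of 0.815. A promoter width of 2.5 kb gave open shares of 68.1% and 20.2%. The list passing IDR between replicates gave 8 lists with more promoter peaks, and the background of the same CpG class 8 with more and 4 with fewer in place of 7. Dinucleotide shuffles left 0 motifs less frequent at promoters and 0 at distal summits, and NEUROD turned to 0.223 points (adjusted exact p = 0.596). Windows of 100 bp gave 8 less frequent motifs at promoters in place of 5. Leaving out each replicate in turn gave 4 to 8 lists with more promoter peaks, 7 to 12 lists with more distal regions in place of 11 (15 with the 100 kb window), and open shares of 67.6% to 74.7% and 18.5% to 25.1%.

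The difference between primary and other granule genes passed no threshold and turned direction, from 8.44 points to −4.55 with the less strict lists and −6.49 with the stronger peaks. For single gene lists and motifs, 137 of 176 promoter, 113 of 132 distal and 268 of 300 motif alternatives kept their side of the threshold; 12, 12 and 14 lost it, 25, 7 and 17 gained it, and 2, 0 and 1 turned direction.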

Other observations

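The comparisons of B cell with T cell and other blood cell genes, the promoter share at equal numbers of regions, the search for repeated 31-mers and the CTCF count in the 100 strongest regions were chosen only after the results they bear on had been seen. The other tests of explanations below were written down before, although comparisons of motifs between deciles, as for CTCF, were added after the data were examined. The genes and motifs of the first 2 paragraphs, and Cd79a, Ms4a1 and Cd74, were picked after their values were seen. Genes with many distal regions did not always have an open promoter. The share of genes with an open promoter was 24.2% among the 10641 genes with no distal region within 50 kb (95% Wilson interval 23.4 to 25.1), 52.5% among 7646 genes with a mean of 0.5 to 1.5, 58.9% among 2926 genes with 2 to 3.5 and 56.0% among 698 genes with 4 or more (52.3 to 59.7). Of these 698 genes, 210 had no promoter peak in either replicate. Among the listed genes they included the transcription factor genes Cebpb and Fli1, with a mean of 7 distal regions each. They also included Ifitm3 with 6, the cytokine genes Tnf with 5.5 and Il1b with 5, the adhesion gene Selp with 5, and Tlr2, the receptor for bacterial lipoproteins, with 4. In the less strict lists Cebpb had promoter peaks of 3.42 and 5.19 in the 2 replicates and Tlr2 of 4.28 and 5.34, while Fli1, Tnf and Il1b had one in replicate 1 alone.

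Open regions were densest on chromosome 11, with 13.5 ± 5.59 per Mb (SD, n = 2), followed by chromosome 19 with 11.8 ± 5.51 and chromosome 17 with 11.2 ± 4.73. Chromosome X had 2.69 ± 1.19 per Mb and chromosome Y 0.0981 ± 0.0154. At promoters the AP-1 motif was in 0.989% of the strongest decile and 4.20% of the weakest decile of replicate 1 (adjusted exact p = 1.09e-05), and in 1.11% and 2.44% in replicate 2 (adjusted exact p = 0.229). At distal regions the interferon element ISRE was in 2.89% of the strongest and 1.16% of the weakest decile of replicate 1 (adjusted exact p = 0.0054), and in 1.27% and 1.99% in replicate 2 (adjusted exact p = 0.819), so that this order held in replicate 1 alone.

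Promoters of B cell genes were open at 11 of 18 genes, a share that passed the test within their CpG class, while the T cell list had 2 of 20. Peaks of neighbouring protein-coding genes are argued against, since 0 of the 11 peaks of replicate 1 lay within 1 kb of another protein-coding gene's start site. The exact upper limit was 28.5%, and 26.4% of all open genes had such a peak. Start sites of noncoding genes were not searched. A general mixture of other blood cells stays open, since promoters and distal regions point different ways. That the B cell share was above that of T cells (exact p = 0.00162) restates the pattern. The share was also above the natural killer cell and erythroid lists (both adjusted exact p = 6.00e-04), the megakaryocyte and eosinophil lists (both 0.0039) and the monocyte list (0.0178). Against the dendritic cell and MHC class II list, open at 42.9%, the B cell share of 61.1% was higher but did not pass (adjusted exact p = 0.4765). Distal regions passed the threshold near megakaryocyte (adjusted permutation p = 0.016), eosinophil (0.0221) and dendritic cell (1.10e-04) genes. Near T cell genes they did not within 50 kb (adjusted permutation p = 0.524) but did within 100 kb (adjusted permutation p = 0.0451). The megakaryocyte (adjusted permutation p = 0.053) and eosinophil (0.139) calls were lost with the less strict lists. Neighbouring members of a list can count the same distal regions, so these p values may be too small. B cells in the samples are a candidate source that cannot be told apart from open promoters of the neutrophils themselves. In replicate 1, only 2 of 52 distal regions near B cell genes held an EBF or OCT motif (3.85% against 2.19% elsewhere, odds ratio 1.78, exact p = 0.317), too few to decide. Over all distal summits both motifs were more frequent than in the flanks, OCT at 1.501% against 0.498% and EBF at 0.492% against 0.213%. The EBF call was lost with the stronger peaks alone. Which cells held these motifs was not tested. The signal values of genes abundant in B cells were 12.7 and 11.3 at Cd79a, 13.0 and 11.4 at Ms4a1 and 5.46 and 6.55 at Cd74. No B cell list gene is on another list, how many of the 18 neutrophils express was not measured here, and the labels name no sort or gate that would remove B cells.

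Replicate 2 had a lower share of distal regions than replicate 1. If fewer called peaks at an equal ranking were the whole cause, the strongest 14548 regions of replicate 1 would have the promoter share of replicate 2 (62.0%); they had 51.2% (95% Wilson interval 50.4 to 52.0), below the midpoint of 52.9% between the replicates, which argues against it as the whole cause. Among the shared regions, the 5451 distal ones moved down in percentile rank from replicate 1 to replicate 2 by a median of 7.14 (−7.14) and the 8823 promoter ones up by 4.86, a difference of −12 points (bootstrap interval −12.7 to −11.3), which is what distal regions weaker relative to promoters in replicate 2 would give. The ranks and the called peaks come from the same 2 lists, so this shift describes the pattern again and does not explain it. The interval covers resampling of regions, which are not independent replicates. Why the distal regions ranked lower stays open: depth, background in the library and the makeup of the cells could each do so, and none was measured here. The design names 1 group, so no biological explanation was tested.

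Among regions passing IDR between replicates, the 2 with the highest signal value lay far from genes, at chromosome X, 143482937 to 143483175 (signal value 42.6; 35534 bp from the start site of Pak3), and at chromosome 2, 69355474 to 69355729 (40.05; 12985 bp from that of Abcb11). Reads of repeated copies piled on one place may account for part of the strongest regions: the 31-mer at the summit occurred more than once on the 21 assembled chromosomes for 15 of the 100 strongest, or 15%, against 2.27% of the other 24782 (odds ratio 7.59, exact p = 1.06e-08), and for 8 of the 20 strongest, though for neither of the 2 above. Sequences outside the 21 assembled chromosomes, such as the mitochondrial genome, were not part of this count. Copies there are therefore not excluded for those 2 regions. A first search over all 239 sequences of the reference, narrowed afterwards because patches and alternate loci repeat the chromosomes, gave 18 of 100 against 6.77% (odds ratio 3.02, exact p = 1.32e-04). The CTCF string was not seen more often in the strongest regions. It was in 10.8% of the strongest and 11.3% of the weakest decile of distal regions (difference −0.453 points, 95% interval −2.84 to 1.93, exact p = 0.756). It was also in 4 of the 100 strongest of all regions (95% Wilson interval 1.57% to 9.84%) against 9.16% of the others (exact p = 0.0808). Because a fixed string finds only some sites, these shares cannot show how many of the strongest regions hold a CTCF site. What made the rest of the strongest regions strong stays open. With 1 group, no biological difference between samples was tested.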
